A study of Mus musculus with 11 samples.

How the data were processed

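Small RNA was measured by sequencing in 11 mouse libraries, made per the labels from RNA of cauda epididymal sperm, superovulated WT oocytes and 2PN embryos obtained by sperm injection, on the C57BL/6 background. The series description names the Ion Torrent Proton platform and says that profiles were made in duplicate, whereas the sample labels give 2 WT, 2 Dicer cKO and 3 Drosha cKO sperm libraries and 1 library for each of oocyte and the 3 kinds of 2PN embryo; the labels were followed. The labels do not say whether libraries of a group came from separate animals, so p-values measure the spread between these samples.

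The count table, as deposited by the authors, held raw reads per feature for 1592 mature miRNAs and 712 endo-siRNAs. The authors also made a table of RPM values, in which each count was divided by 1 whole number per library and scaled to RPM; the values matched such a divisor to within 0.0054 of a whole number. The divisors ran from 412523 to 3743577, and what they count is not given in the sources used here. Listed reads made up 2.16% and 10.1% of the divisor in WT sperm, 4.43% and 7.01% in Dicer cKO sperm, 2.11% to 2.91% in Drosha cKO sperm, and 0.196% to 0.737% in oocyte and 2PN libraries. Bowtie and the build mm10 are named in the submitters' notes; versions, the counting rule, the miRNA release and the origin of the endo-siRNA list are not given in the sources used here. Coordinates came from a RefSeq gene table on GRCm38, to which 1400 of the 1592 mature miRNAs were matched through their hairpin names. A genome on another build was not used here.

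Sperm comparisons used the counts of all 7 sperm libraries in edgeR 4.0.16 under R 4.3.3, with TMM factors, the default expression filter (335 features tested, 321 of them miRNAs and 14 endo-siRNAs) and the quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment at a threshold of 0.05. The biological coefficient of variation was 0.459. TMM factors were 0.899 and 0.497 in WT, 1.05 and 1.06 in Dicer cKO and 1.19 to 1.30 in Drosha cKO sperm. Replicates varied beyond counting error, with chi-square per degree of freedom from 7.19 to 54.4. With 200 of 335 features changed in simulations, 11.3% and 13.4% of 2-fold changes were recovered for Dicer and Drosha. At 4-fold these were 53.6% and 50.7%, at 8-fold 84.8% and 86.1%, with 1.67% and 2.08% of calls false. The rates may not hold where falls dominate WT reads, as here. Log2 changes use TMM factors, and CPM means and SDs use listed reads alone.

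Before the data were examined, 14 miRNA lists were fixed: the miR-34 and miR-449 family, X-linked testis miRNAs, the let-7 family, the miR-17-92 and paralog clusters, the cluster of miR-183, miR-96 and miR-182, the Dlk1-Dio3, Sfmbt2 and miR-290-295 clusters, the group of miR-10, miR-99, miR-100 and miR-125, the miR-30 family, miRNAs made without Drosha's complex, and markers of epithelial, stromal and blood cells. The endo-siRNAs formed 1 more list. Lists with at least 3 tested members were tested with camera from limma 3.58.1 at a preset correlation of 0.01, then with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists. With an estimated correlation no list passed in any comparison. By fry, whose test asks whether a list's members move 1 way, the highest adjusted p among lists called by camera was 0.0341 for Dicer, for the Sfmbt2 cluster, and 0.0524 for Drosha, for the same cluster. None of the 4 lists that camera placed apart between Dicer cKO and Drosha cKO passed fry (adjusted p = 0.149 for blood cell markers and the miR-30 family, 0.207 for the miR-34 and miR-449 family and the endo-siRNAs). In simulations that drew each feature independently, camera found a raised list of 20 members in 100% of 50 runs and an unchanged list in 2%. In the data the estimated correlation reached 0.745, for the Sfmbt2 cluster in Drosha cKO sperm. The simulated rates therefore do not carry over to lists whose members vary together. Also fixed then were the comparisons, the tests, most alternatives and the rule for named features. That rule took, among called features with a mean of at least 10 CPM and groups that do not overlap, the 8 largest falls and 8 largest rises, then the 8 most abundant features of WT sperm, and up to 4 most abundant members of each list. For oocyte and 2PN comparisons it took the 8 largest rises and falls among features with at least 50 reads in 1 of the 2 libraries.

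The overlap of Dicer and Drosha calls was set against 100 simulations of unchanged groups tested against the same WT libraries. Oocyte and 2PN libraries have no replicates, so only values are given, as shares of listed reads or ratios of CPM with a floor of 3 reads, with 95% exact (Clopper-Pearson) intervals for shares and exact intervals for ratios of counts. A fold against 0 reads is a bound computed at 3 reads, and a printed fold with 1 to 3 reads is the ratio of the reads as counted. The bound takes the other count as it stands, so it is no lower confidence limit. Intervals and floors cover counting error only. List medians in 2PN were ranked among 10000 random lists matched on mean expression. A feature was detected at 3 reads and 10 CPM and absent at 0 reads.

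Alternatives were library totals without TMM, DESeq2 1.42.0 size factors in edgeR, no low-count filter, at least 10 CPM in 2 libraries, the DESeq2 test, limma on log2 of RPM plus 1, only the 2 groups compared, the replicate number as a block, and each library left out in turn. Other thresholds on reads, floors, detection limits and depth were used for oocyte and 2PN libraries. Chosen after seeing the data were the authors' divisor as library size, miRNAs only, a mean of at least 200 CPM, and leaving out the 2 shallow Drosha cKO libraries. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.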

Results

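Small RNAs were sequenced from mouse sperm, oocytes and 2PN (pronuclear) embryos in 11 libraries. Sperm came from the cauda epididymis of wild-type (WT) males in 2 libraries, of males with a germline conditional knockout (cKO) of Dicer in 2 libraries, and of males with a cKO of Drosha in 3 libraries. Drosha cuts miRNA hairpins out of their primary transcripts in the nucleus, and Dicer cuts the hairpins, and long double-stranded RNA, into mature small RNAs in the cytoplasm. WT oocytes and 2PN embryos made by sperm injection with WT, Dicer cKO or Drosha cKO sperm gave 1 library each, so their values have no replicate error. The count table listed 2304 features, of which 1592 were mature miRNAs and 712 were endogenous siRNAs (endo-siRNAs). Messenger RNA was not measured, so the loss of Dicer or Drosha itself was not checked.

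Listed reads numbered 73377 and 278890 in the WT sperm libraries, 122989 and 108141 in Dicer cKO sperm, and 100934, 12003 and 15921 in Drosha cKO sperm. The oocyte library held 5530 listed reads. The 2PN libraries from WT, Dicer cKO and Drosha cKO sperm held 3243, 2951 and 8967. A floor of 3 reads corresponded to 10.8 to 249.9 CPM (counts scaled to listed reads) in sperm and to 334.6 to 1016.6 CPM in oocytes and 2PN embryos. miR-19b-3p, a member of the miR-17-92 cluster, was the most abundant feature in both WT sperm libraries, at 9.14% and 10.1% of listed reads. In cKO sperm the most abundant feature was miR-10a-5p or miR-200c-3p, depending on the library. miR-30c-5p led in the oocyte library, at 27.3% (95% exact interval 26.1 to 28.5), and in all 3 2PN libraries. Across features, the Pearson correlation of log2 CPM was 0.903 between the WT sperm libraries, 0.97 between the Dicer cKO libraries and 0.859 to 0.902 among the Drosha cKO libraries. It was 0.449 to 0.605 between WT and cKO libraries and 0.844 to 0.904 between Dicer cKO and Drosha cKO libraries; features are not independent replicates.

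The first comparison asked which sperm small RNAs depend on Dicer in the male germ line. Many of the miRNAs abundant in WT sperm, but not all of them, were depleted in Dicer cKO sperm. The miR-34 and miR-449 family, which is enriched in male germ cells and ciliated epithelia, fell from 17.2% ± 1.29 (SD, n = 2) of listed reads in WT sperm to 1.30% ± 0.063 (n = 2). The X-linked miRNAs near Fmr1, which are expressed in the testis, fell from 6.76% ± 0.667 to 0.540% ± 0.018, and the miR-17-92 group fell from 20.5% ± 2.50 to 3.69% ± 0.296. Over the same libraries the epithelial miRNAs of the miR-200 and miR-141 group rose from 1.71% ± 0.164 to 14.6% ± 2.16, and the blood cell miRNAs rose from 0.536% ± 0.011 to 5.17% ± 0.002. The edgeR test called 158 of 335 tested features, 104 lower and 54 higher. The 104 lower features held 72.2% and 79.7% of listed reads in the WT libraries and 13.4% and 14.6% in the Dicer cKO libraries.

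In Dicer cKO sperm, 5 of 6 tested members of the miR-34 and miR-449 family fell and 1 rose, with the same counts adjusted over the list alone (median log2 change −5.30). The family's camera adjusted p was 0.00028, with adjusted p = 0.35 with an estimated correlation. miR-34b-5p and miR-34c-5p derive from hairpins on chromosome 9, at 51103562 to 51103645 and 51103034 to 51103110 in GRCm38, within the annotated span of Btg4 and Hoatz. miR-34b-5p stood at 69688 ± 4096 CPM in WT sperm and 3319 ± 197.5 CPM in Dicer cKO sperm (log2 change −5.13, SE 0.533, edgeR adjusted p = 5.11e-06). miR-34c-5p changed by −5.31 (SE 0.551, edgeR adjusted p = 5.11e-06), and the related miR-449a-5p by −5.28 (SE 0.621, edgeR adjusted p = 1.62e-05). All 27 tested X-linked testis miRNAs fell, and all 27 did so adjusted over the list alone (median −4.29, camera adjusted p = 6.96e-12; adjusted p = 0.32 with an estimated correlation). Among them, miR-743a-3p fell by 4.99 on the log2 scale (SE 0.606), miR-743b-3p fell by 5.15, miR-880-3p fell by 4.40 (SE 0.629) and miR-741-3p fell by 3.53. Of 30 tested miRNAs from the cluster in an intron of Sfmbt2, 29 fell, also adjusted over the list alone (median −4.55, camera adjusted p = 4.17e-08; adjusted p = 0.408 with an estimated correlation). Examples are miR-669a-3p (−4.80, SE 0.715), miR-467e-5p (−4.30), miR-466a-3p (−4.65) and miR-466b-3p (−4.75). Members of this cluster are nearly identical in sequence and the counting rule is not given in the sources used here, so reads may be shared among them. In the same libraries the epithelial and blood cell marker lists moved upward, with medians of 2.37 and 2.55.

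Of 11 tested members of the miR-17-92 and paralog clusters, which are expressed in dividing cells, 7 fell and 4 did not pass the test in Dicer cKO sperm. Adjusted over the list alone, 9 fell and 1 rose (median −2.86, camera adjusted p = 0.0025; adjusted p = 0.432 with an estimated correlation). miR-19b-3p fell from 96283 ± 6956 CPM to 18238 ± 1874 CPM (log2 change −3.14, SE 0.457, edgeR adjusted p = 0.000113). miR-19a-3p fell by 4.11 on the log2 scale (SE 0.559), miR-18a-5p fell by 5.01 (SE 0.574) and miR-20a-5p fell by 2.86. Both tested members of the miR-290-295 cluster, which marks early embryos and embryonic stem cells, were called lower, also adjusted over the list alone. miR-294-3p changed by −4.73 (SE 1.109, edgeR adjusted p = 0.00176), on 2 reads against 51 in WT (30.4-fold lower, counting interval 7.99 to 258), and its call was lost without Dicer cKO replicate 2 (adjusted p = 0.0555). miR-293-3p had 0 reads in both Dicer cKO libraries and was at least 25.4-fold lower, with a floor of 3 reads over the group. The pair had a median of −6.22 as fitted and −4.70 with miR-293-3p at its bound. Other abundant WT sperm miRNAs fell as well, with log2 changes for miR-191-5p of −2.50 (SE 0.537), for miR-16-5p of −2.66 (SE 0.588), for miR-15b-5p of −2.81 (SE 0.555) and for miR-30b-5p of −1.60 (SE 0.526). The call of miR-30b-5p was lost without Dicer cKO replicate 1 (edgeR adjusted p = 0.0941). In the miR-30 family 3 of 7 tested members fell, also adjusted over the list alone, and 4 did not pass the test (median −0.64, which turned to 0.04 with library totals alone; camera adjusted p = 0.594). The 3 became 1 without WT replicate 2, 0 without Dicer cKO replicate 1 and 0 with the authors' library divisor. miR-30c-5p changed by −1.33 (SE 0.508, edgeR adjusted p = 0.0403). It lost its call without any 1 library except WT replicate 1. miR-30d-5p (−0.49) and miR-30a-5p (0.55) did not pass the test. With limma on RPM the calls of miR-19b-3p, miR-20a-5p, miR-191-5p, miR-16-5p, miR-15b-5p, miR-30b-5p and miR-30c-5p were lost, and with the authors' divisor all of these except the first pair. Without a low-count filter miR-191-5p, miR-16-5p, miR-30b-5p and miR-30c-5p lost theirs, with library totals alone or at least 10 CPM in 2 libraries miR-30b-5p and miR-30c-5p did, and with only the 2 groups compared miR-30c-5p did. Other abundant miRNAs did not fall: miR-29a-3p and miR-29b-3p, looked up after their values were seen, changed by 1.22 (SE 0.449, edgeR adjusted p = 0.0351) and 1.17 (SE 0.425, edgeR adjusted p = 0.0326). Both calls were lost without WT replicate 1, Dicer cKO replicate 1 or Dicer cKO replicate 2 (highest adjusted p = 0.359 and 0.489, without Dicer cKO replicate 1), without a low-count filter, and with DESeq2, limma, the authors' divisor or miRNAs only.

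Of 8 tested epithelial markers of the miR-200 and miR-141 group, 7 rose in Dicer cKO sperm, also adjusted over the list alone (median 2.37, camera adjusted p = 0.000627; adjusted p = 0.32 with an estimated correlation). miR-200c-3p rose from 8252 ± 357 CPM to 63572 ± 1376 CPM (log2 change 2.24, SE 0.444, edgeR adjusted p = 0.000787). miR-200b-3p rose by 2.50 (SE 0.534), miR-200a-3p by 2.59 (SE 0.576), and miR-141-3p, from a hairpin on chromosome 6 at 124717914 to 124717985, by 2.56 (SE 0.559). Without Dicer cKO replicate 1 or without Dicer cKO replicate 2, 4 of the 8 were called. Of 8 tested blood cell markers, 5 rose, and 6 did so adjusted over the list alone (median 2.55, camera adjusted p = 0.000627; adjusted p = 0.255 with an estimated correlation); without Dicer cKO replicate 1, 3 were called. miR-451a, a red cell miRNA that is cut by Ago2 and not by Dicer, rose from 2414 CPM to 30094 CPM (log2 change 3.07, SE 0.496, edgeR adjusted p = 0.000239). Its cluster partner miR-144-3p rose by 2.86 (SE 0.71) and the lymphocyte miRNA miR-150-5p by 4.02 (SE 0.686), while miR-142-3p, another leukocyte miRNA, stood at 1.13 and did not pass the test. Of 7 tested stromal and smooth muscle markers, 2 rose, 1 of them adjusted over the list alone (median 1.01, camera adjusted p = 0.095). miR-145a-5p changed by 1.90 (SE 0.587, edgeR adjusted p = 0.0142), and the call was lost without WT replicate 2 and without Dicer cKO replicate 1 (highest adjusted p = 0.399, without the latter). miR-143-3p changed by 1.58 (SE 0.590, edgeR adjusted p = 0.0369), and the call was lost without either WT or either Dicer cKO library (highest adjusted p = 0.368, without Dicer cKO replicate 2). The list count was 1 without WT replicate 1 or Dicer cKO replicate 2, and 0 without WT replicate 2 or Dicer cKO replicate 1; camera called the list without WT replicate 1 (adjusted p = 0.0275). Both calls were also lost without the shallow Drosha cKO libraries, and that of miR-143-3p without a low-count filter, with the authors' divisor and with miRNAs only. miR-199a-3p and miR-199a-5p were not called.

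Of 8 tested members of the group of miR-10, miR-99, miR-100 and miR-125, which is abundant in somatic and epithelial tissue, 6 rose in Dicer cKO sperm, also adjusted over the list alone. The group's median was 1.58 (camera adjusted p = 0.00406; adjusted p = 0.408 with an estimated correlation). miR-10a-5p, from a hairpin on chromosome 11 at 96317165 to 96317274 within Hoxb3, rose from 8291 CPM to 68178 CPM (log2 change 2.43, SE 0.467, edgeR adjusted p = 0.000693). miR-10b-5p rose by 2.42 (SE 0.477). miR-125b-5p changed by 1.41 (SE 0.438, edgeR adjusted p = 0.0147) and miR-99a-5p by 1.66 (SE 0.627, edgeR adjusted p = 0.0394). Both calls were lost without WT replicate 2, Dicer cKO replicate 1 or Dicer cKO replicate 2, with highest adjusted p = 0.359 and 0.439, and without the shallow Drosha cKO libraries. That of miR-125b-5p was lost as well without a low-count filter and with the authors' divisor, and that of miR-99a-5p with DESeq2, its size factors, miRNAs only or a mean of at least 200 CPM. The group's count was 2 without each of these 3 libraries and 2 without the shallow Drosha cKO libraries. In the let-7 family, which is broad in differentiated cells, 3 of 14 tested members rose, 2 of them adjusted over the list alone (median 0.57, camera adjusted p = 0.0616). The count was 1 without WT replicate 2 (camera adjusted p = 0.0415) or Dicer cKO replicate 2, and 0 without Dicer cKO replicate 1; without Drosha cKO replicate 1 camera also called the list (adjusted p = 0.0437). let-7c-5p changed by 1.94 (SE 0.439, edgeR adjusted p = 0.00183) and lost its call without Dicer cKO replicate 1 (adjusted p = 0.11). let-7f-5p changed by 1.28 (SE 0.472, edgeR adjusted p = 0.0353) and lost it without either WT or either Dicer cKO library (highest adjusted p = 0.361, without Dicer cKO replicate 1), without a low-count filter, and with DESeq2, its size factors, limma, the authors' divisor or miRNAs only. let-7a-5p (−0.36) and let-7g-5p (0.35) did not pass the test. Epithelial markers rose beside these groups.

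No tested member of the remaining miRNA lists passed the edgeR test over all features in Dicer cKO sperm. The cluster of miR-183, miR-96 and miR-182 had a median of 1.46 over 3 members (camera adjusted p = 0.251), and 2 members rose adjusted over the list alone. The imprinted Dlk1-Dio3 cluster had a median of −0.39 over 4 members, which turned to 0.36 with library totals alone and to 0.22 with the authors' divisor; camera placed it upward relative to the other features although its mean was −0.43 (adjusted p = 0.98), and 0 passed adjusted over the list alone. The 3 tested miRNAs that are made without Drosha's complex had a median of 0.26 (camera adjusted p = 0.55), with 0 past the test adjusted over the list alone. They were miR-484 at −0.22, miR-320-3p at 1.76 and miR-1981-5p at 0.26. Of 14 tested endo-siRNAs, 1 rose and 2 fell, and 1 rose and 1 fell adjusted over the list alone (median 0.01, mean −0.54, camera adjusted p = 0.663). endo-siRNA-Sp392 changed by −1.67 (SE 0.638, edgeR adjusted p = 0.0403), and the call was lost without WT replicate 1, without either Dicer cKO library, and without Drosha cKO replicate 1 or 3 (highest adjusted p = 0.218, without Dicer cKO replicate 2). It was also lost with library totals alone, both other low-count filters, limma, only the 2 groups compared and the authors' divisor. The endo-siRNA median turned negative without WT replicate 2 (−1.11), Dicer cKO replicate 1 (−0.68) or Dicer cKO replicate 2 (−1.10), with DESeq2 size factors (−0.16) and without the shallow Drosha cKO libraries (−1.57). It did so too without a low-count filter (−2.17 over 711 endo-siRNAs, camera adjusted p = 1.4e-13; 0.459 with an estimated correlation and 0.299 by fry) and with at least 10 CPM in 2 libraries (−2.09 over 157, camera adjusted p = 0.00047; 0.402 with an estimated correlation and 0.241 by fry). Of these 711, all had a read in WT replicate 1, 511 of them 1 read, and 263 had a read in any other sperm library (160 in WT replicate 2, 77 and 63 in Dicer cKO sperm). Without the filter the median in Drosha cKO sperm was −2.17 as well (camera adjusted p = 2.35e-06; 0.567 with an estimated correlation). In RPM the list summed to 561 and 545 in WT and to 706 and 816 in Dicer cKO sperm. endo-siRNA-Sp527 alone held 31.95% and 47.29% of endo-siRNA reads in WT and 73.87% and 69.71% in Dicer cKO sperm. The sum therefore follows this entry and does not describe the other endo-siRNAs, whose fall is neither shown nor excluded by it.

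The largest falls in Dicer cKO sperm, beside miR-293-3p and the minor arms miR-34c-3p (−5.67, SE 0.837) and miR-34b-3p (−5.62, SE 0.582), included miRNAs that belong to none of the lists. miR-296-5p, from chromosome 2 at 174267047 to 174267125, fell by 6.51 on the log2 scale (SE 0.933, edgeR adjusted p = 9.56e-05). miR-184-3p, from chromosome 9 at 89802260 to 89802328, fell from 2266 CPM to 60.8 CPM (log2 change −5.83, SE 0.740). miR-669m-3p (−6.23, SE 1.311) and miR-297c-5p (−5.90, SE 1.408) belong to the Sfmbt2 cluster and had 1 read each over the Dicer cKO libraries, so their ratios were 123-fold (counting interval 21.5 to 4890) and 91.7-fold lower (16.0 to 3670). endo-siRNA-Sp105 had 0 reads in both Dicer cKO libraries and was at least 9.53-fold lower (edgeR adjusted p = 0.00477). Among the largest rises, miR-6914-3p had 0 reads in both WT libraries and was at least 18.2-fold higher (edgeR adjusted p = 0.000882). The neuronal miRNA miR-137-3p changed by 4.05 (SE 1.163, edgeR adjusted p = 0.00698) and lost its call without Dicer cKO replicate 2. With 2 WT reads its ratio was 17.6-fold (counting interval 4.59 to 150). miR-5121 changed by 3.18 (SE 0.738, edgeR adjusted p = 0.00199) and lost its call without WT replicate 2. endo-siRNA-Sp453 (3.87, SE 1.214, edgeR adjusted p = 0.0119) and miR-5621-5p (3.25, SE 0.943, edgeR adjusted p = 0.00828) lost theirs without WT replicate 2 or either Dicer cKO library, with adjusted p up to 0.228 and 0.107. miR-6918-3p (3.40, SE 1.166, edgeR adjusted p = 0.0184) lost it without either WT library or Dicer cKO replicate 1, with adjusted p up to 0.295. miR-200a-5p (3.21, SE 1.164, edgeR adjusted p = 0.0265) lost it without WT replicate 1 or either Dicer cKO library, with adjusted p up to 0.148. endo-siRNA-Sp453, miR-6918-3p and miR-200a-5p had 2, 2 and 3 WT reads, with ratios of 18.5-fold (counting interval 4.82 to 157), 12.2-fold (3.08 to 105) and 9.51-fold (2.99 to 48.4). Their calls were also lost with DESeq2, those of miR-6918-3p and miR-200a-5p without a low-count filter, and those of endo-siRNA-Sp453 and miR-6918-3p without the shallow Drosha cKO libraries.

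Of the 52 named and called features in Dicer cKO sperm, 16 lost the call without at least 1 library. The count of rises was the less stable direction: 33 without WT replicate 2, 19 without Dicer cKO replicate 1 and 23 without Dicer cKO replicate 2, against 54 with all libraries. With library totals alone the median of all tested features moved from 0.03 to 0.62 and the rises made up 52.6% of calls in place of 34.2%; with the authors' divisor the median was 0.88 and the rises made up 36.6%.

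**Figure D1:**
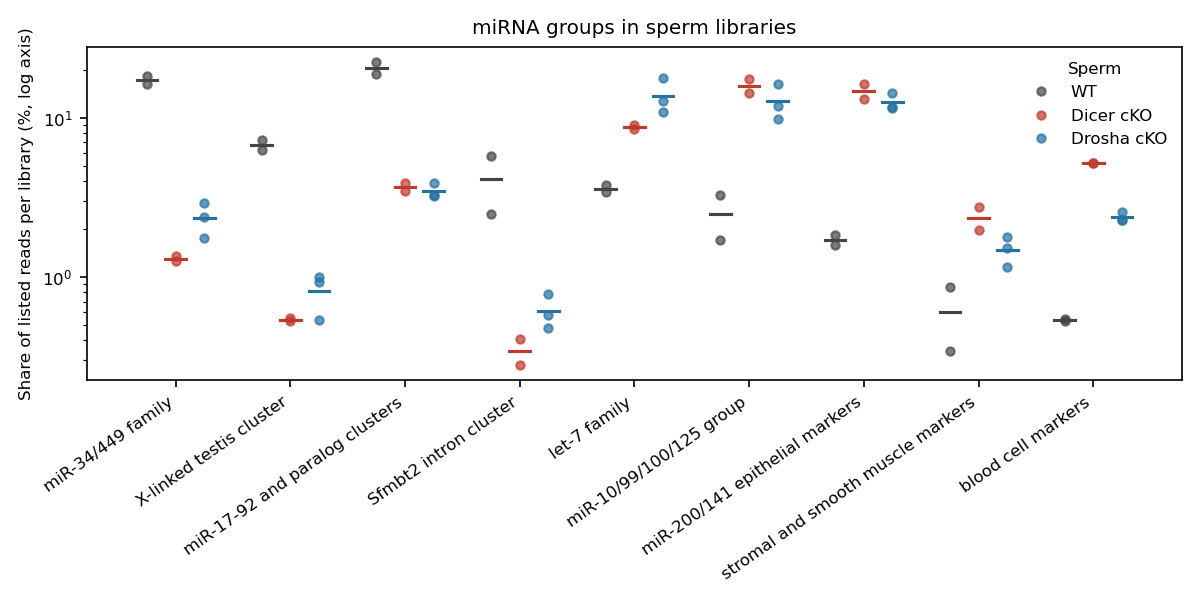
Share of listed reads (%, log axis) held by 9 fixed lists in each sperm library; dots are libraries, lines are group means, WT (n = 2) in grey, Dicer cKO (n = 2) in red and Drosha cKO (n = 3) in blue. The miR-34 and miR-449 family lies at 17.2% in WT sperm and at 1.30% and 2.35% in the cKO groups, while the epithelial markers lie at 1.71%, 14.6% and 12.5%.

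The second comparison asked which sperm small RNAs depend on Drosha. As in Dicer cKO sperm, many abundant germ cell miRNAs fell in Drosha cKO sperm. The miR-34 and miR-449 family fell from 17.2% ± 1.29 (SD, n = 2) of listed reads to 2.35% ± 0.575 (n = 3), the X-linked testis miRNAs from 6.76% ± 0.667 to 0.818% ± 0.249, and the miR-17-92 group from 20.5% ± 2.50 to 3.46% ± 0.369. The epithelial miR-200 and miR-141 group rose from 1.71% ± 0.164 to 12.5% ± 1.57. The let-7 family held 3.57% ± 0.243 in WT and 13.7% ± 3.48 in Drosha cKO sperm. The edgeR test called 185 of 335 features, 111 lower and 74 higher. The 111 lower features held 75.6% and 81.9% of listed reads in the WT libraries and 18.0%, 13.8% and 16.4% in the Drosha cKO libraries.

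In Drosha cKO sperm, 5 of 6 tested members of the miR-34 and miR-449 family fell; adjusted over the list alone, 5 fell and 1 rose (median −3.87, camera adjusted p = 0.000567; adjusted p = 0.425 with an estimated correlation). miR-34b-5p stood at 7599 ± 1619 CPM (log2 change −4.18, SE 0.433, edgeR adjusted p = 9.89e-06) and miR-34c-5p at 5907 ± 2173 CPM (log2 change −4.19, SE 0.444, edgeR adjusted p = 9.89e-06). miR-449a-5p fell by 3.82 on the log2 scale (SE 0.499) and miR-34b-3p fell by 3.65 (SE 0.454). All 27 tested X-linked testis miRNAs fell, all 27 also adjusted over the list alone (median −4.15, camera adjusted p = 1.15e-11; adjusted p = 0.425 with an estimated correlation). miR-743a-3p fell by 4.55 (SE 0.511, edgeR adjusted p = 1.08e-05), miR-743b-3p fell by 4.36, miR-880-3p fell by 3.49 and miR-741-3p fell by 3.11 on the log2 scale. In the Sfmbt2 cluster 28 of 30 tested members fell, also adjusted over the list alone (median −3.86, camera adjusted p = 5.24e-06; adjusted p = 0.425 with an estimated correlation). miR-669a-3p changed by −4.46 (SE 0.603), miR-467e-5p by −4.38, miR-466a-3p by −4.28 and miR-466b-3p by −4.38. The epithelial marker list rose in the same libraries, with a median of 1.92.

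Of 11 tested miR-17-92 and paralog members, 9 fell in Drosha cKO sperm, also adjusted over the list alone (median −3.10, camera adjusted p = 0.000213; adjusted p = 0.425 with an estimated correlation). miR-19b-3p stood at 15998 ± 855 CPM (log2 change −3.59, SE 0.399, edgeR adjusted p = 1.08e-05). miR-19a-3p and miR-18a-5p, whose hairpins lie on chromosome 14 at 115044000 to 115044081 and 115043851 to 115043946, changed by −4.17 (SE 0.479) and −4.05 (SE 0.469), and miR-20a-5p by −3.38. In the miR-30 family 5 of 7 tested members fell, also adjusted over the list alone (median −2.17, camera adjusted p = 0.0614). miR-30c-5p changed by −2.59 (SE 0.462, edgeR adjusted p = 0.00034), miR-30b-5p by −2.66 (SE 0.473) and miR-30d-5p by −1.42 (SE 0.403), while miR-30a-5p stood at −0.40 and did not pass the test. The call of miR-30d-5p was lost with library totals alone, without a low-count filter, with limma and with the authors' divisor. Camera called the family without WT replicate 1 (adjusted p = 0.0332) or Dicer cKO replicate 1 (adjusted p = 0.0408), without the shallow Drosha cKO libraries (0.042), with DESeq2 size factors (0.0466), and with both other low-count filters (0.000172 and 0.00442). Both miR-290-295 members fell, also adjusted over the list alone (median −5.20), with miR-293-3p at −5.33 (SE 1.163) and miR-294-3p at −5.06 (SE 1.248). Each had 1 read over the Drosha cKO libraries, giving ratios of 49.0-fold (counting interval 8.49 to 1970) and 39.1-fold lower (6.70 to 1570). miR-15b-5p, from chromosome 3 at 69009772 to 69009835 within Smc4, changed by −3.48 (SE 0.491). miR-16-5p changed by −3.13 (SE 0.516), and miR-191-5p, from chromosome 9 at 108568319 to 108568392 within Dalrd3, by −2.41 (SE 0.465, edgeR adjusted p = 0.000608).

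All 8 tested epithelial markers rose in Drosha cKO sperm, also adjusted over the list alone (median 1.92, camera adjusted p = 0.00258; adjusted p = 0.425 with an estimated correlation). miR-200c-3p stood at 57690 ± 9785 CPM (log2 change 1.84, SE 0.415, edgeR adjusted p = 0.00181) and lost its call without WT replicate 1. miR-200b-3p (1.94, SE 0.497, edgeR adjusted p = 0.00423) also lost it without WT replicate 1. miR-200a-3p (1.90, SE 0.534, edgeR adjusted p = 0.00747) lost it without WT replicate 1 or Dicer cKO replicate 1 (adjusted p up to 0.249). miR-141-3p (1.47, SE 0.51, edgeR adjusted p = 0.0233) lost it without WT replicate 1 or either Dicer cKO library (adjusted p up to 0.565). All 4 calls were also lost with the authors' divisor and without a low-count filter, all except that of miR-200c-3p without the shallow Drosha cKO libraries, those of miR-200c-3p and miR-141-3p with limma, and that of miR-141-3p with at least 10 CPM in 2 libraries or only the 2 groups compared. The list count was 1 without WT replicate 1 (camera adjusted p = 0.0154), 3 without Dicer cKO replicate 1 and 4 without Dicer cKO replicate 2. It was also 1 with the authors' divisor (camera adjusted p = 0.0048) and 1 without the shallow Drosha cKO libraries (camera adjusted p = 0.00791).

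Of 8 tested blood cell markers, 4 rose and 1 fell in Drosha cKO sperm, and 5 rose and 1 fell adjusted over the list alone (median 1.72, camera adjusted p = 0.0628). miR-150-5p changed by 2.69 (SE 0.636, edgeR adjusted p = 0.0026) and miR-144-3p by 2.24 (SE 0.666, edgeR adjusted p = 0.00983), and both calls were lost without WT replicate 1. miR-451a changed by 1.41 (SE 0.442, edgeR adjusted p = 0.013) and lost its call without either WT or either Dicer cKO library. miR-142-3p stood at −0.79 and did not pass the test; the member that fell was its other arm, miR-142-5p (−2.68, edgeR adjusted p = 0.0277), which was looked up after its value was seen. The call of miR-142-5p was lost without WT replicate 2 or Drosha cKO replicate 1 or 2, with library totals alone, with limma and without the shallow Drosha cKO libraries. Without a low-count filter miR-150-5p, miR-144-3p and miR-451a lost their calls, miR-144-3p and miR-451a did so with the authors' divisor, miR-144-3p without the shallow Drosha cKO libraries, and miR-451a with limma, at least 10 CPM in 2 libraries or only the 2 groups compared. Without WT replicate 1 the list had 0 rises and 2 falls, without WT replicate 2 it had 2 rises (camera adjusted p = 0.0362), and without Dicer cKO replicate 1 or 2 it had 2 rises and 1 fall. With the authors' divisor it had 1 of each. None of 7 tested stromal markers passed the edgeR test, over all features or adjusted over the list alone (median 0.65, camera adjusted p = 0.329); the median was −0.39 without WT replicate 2.

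In the let-7 family 5 of 14 tested members rose in Drosha cKO sperm, and 4 adjusted over the list alone (median 1.14, camera adjusted p = 0.0446; adjusted p = 0.425 with an estimated correlation). let-7c-5p changed by 2.30 (SE 0.424, edgeR adjusted p = 0.00045). let-7f-5p changed by 1.90 (SE 0.457, edgeR adjusted p = 0.00281) and lost its call without WT replicate 1 or Dicer cKO replicate 1 (adjusted p up to 0.0725). let-7a-5p (0.05) and let-7g-5p (0.35) did not pass the test. The list's camera call was lost without WT replicate 1 (adjusted p = 0.163, with 3 rises and 2 falls), Dicer cKO replicate 1 (0.0775, with 3 rises and 1 fall), Dicer cKO replicate 2 (0.0807, with 4 rises and 1 fall) and Drosha cKO replicate 2 (0.0692). It was lost as well with the authors' divisor (0.0786, with 2 members called), with only the 2 groups compared (0.0627) and without the shallow Drosha cKO libraries (0.148). Library totals alone gave 11 called members. In the group of miR-10, miR-99, miR-100 and miR-125 3 of 8 tested members rose, 2 of them adjusted over the list alone (median 1.09, camera adjusted p = 0.0614). The group's count was 0 without Dicer cKO replicate 1, 1 without Dicer cKO replicate 2 and 0 with the authors' divisor; camera called it without WT replicate 1 (adjusted p = 0.0348) or Drosha cKO replicate 3 (adjusted p = 0.0338), without the shallow Drosha cKO libraries (0.00683) and without a low-count filter (0.0138). miR-10a-5p changed by 1.83 (SE 0.433, edgeR adjusted p = 0.00267), and the call was lost without Dicer cKO replicate 1 (adjusted p = 0.0575). miR-10b-5p, from chromosome 2 at 74726070 to 74726137, changed by 1.77 (SE 0.442, edgeR adjusted p = 0.0036) and lost its call without WT replicate 1 or either Dicer cKO library (adjusted p up to 0.0847). miR-125b-5p changed by 1.06 (SE 0.406, edgeR adjusted p = 0.0371) and lost it without either WT library, either Dicer cKO library or Drosha cKO replicate 3 (adjusted p up to 0.668). miR-99a-5p stood at 1.13 and did not pass the test. Without a low-count filter all 5 calls named here were lost, and with limma or the authors' divisor all except that of let-7c-5p. That of miR-125b-5p was lost besides with DESeq2, its size factors, at least 10 CPM in 2 libraries, only the 2 groups compared, miRNAs only and without the shallow Drosha cKO libraries. Epithelial markers rose beside both groups.

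All 3 tested members of the cluster of miR-183, miR-96 and miR-182, known from sensory cells, rose in Drosha cKO sperm, also adjusted over the list alone (median 1.66, camera adjusted p = 0.134). miR-96-5p changed by 1.72 (SE 0.638, edgeR adjusted p = 0.031), miR-183-5p by 1.66 (SE 0.670, edgeR adjusted p = 0.0445) and miR-182-5p by 1.45 (SE 0.595, edgeR adjusted p = 0.0486). All 3 calls were lost without either WT or either Dicer cKO library, those of miR-183-5p and miR-182-5p without Drosha cKO replicate 1, and that of miR-182-5p without Drosha cKO replicate 3. The highest adjusted p of a member without 1 library was 0.54, for miR-182-5p without WT replicate 2. All 3 calls were also lost without a low-count filter, with at least 10 CPM in 2 libraries, limma, only the 2 groups compared, the authors' divisor or miRNAs only. The calls of miR-182-5p and miR-183-5p were lost with DESeq2 size factors, and those of miR-182-5p and miR-96-5p without the shallow Drosha cKO libraries. The Dlk1-Dio3 cluster had 0 of 4 members past the test, also adjusted over the list alone (median 0.81, camera adjusted p = 0.412), with miR-369-3p at 1.26. The miRNAs made without Drosha's complex had 0 of 3 past the test, also adjusted over the list alone (median 0.71, camera adjusted p = 0.412), with miR-484 at 0.71, miR-320-3p at 0.43 and miR-1981-5p at 1.20.

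Of 14 tested endo-siRNAs, which are made by Dicer without Drosha, 5 rose in Drosha cKO sperm and 0 fell, and 4 rose adjusted over the list alone (median −0.08, which turned to 0.75 with library totals alone, mean 0.65, camera adjusted p = 0.121). endo-siRNA-Sp527 changed by 2.05 (SE 0.462, edgeR adjusted p = 0.00181), a call that was lost with the authors' divisor and without a low-count filter. In the authors' RPM it stood at 179 and 257.8 in WT sperm, at 522 and 569 in Dicer cKO sperm, and at 1235, 938 and 721 in Drosha cKO sperm. endo-siRNA-Sp521 changed by 3.07 (SE 0.88, edgeR adjusted p = 0.00814) and lost its call without WT replicate 1 (adjusted p = 0.0757), without a low-count filter and without the shallow Drosha cKO libraries. Without WT replicate 1 the list median was 1.57 (camera adjusted p = 0.0206) with 2 rises and 1 fall. The list had 3 rises and 3 falls without WT replicate 2 or Dicer cKO replicate 2, 2 rises and 3 falls without Dicer cKO replicate 1, and 2 rises with the authors' divisor.

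The largest falls in Drosha cKO sperm were mostly X-linked or from the Sfmbt2 cluster. miR-467e-3p, with 1 read over the Drosha cKO libraries against 176 in WT, was 135-fold lower (counting interval 23.9 to 5360; fitted log2 change −6.55, SE 1.222), and the X-linked miR-471-5p, from 66792595 to 66792661, changed by −5.86 (SE 0.971, edgeR adjusted p = 0.000192). miR-465a-5p fell by 5.72 on the log2 scale (SE 0.796), and miR-871-5p fell by 5.06 (SE 0.770). miR-743a-5p (fitted −5.67), miR-742-5p (−5.64) and miR-701-5p (−5.10) also had 1 read each over the Drosha cKO libraries, with ratios of 66.6-fold (counting interval 11.7 to 2660), 82.0-fold (14.4 to 3270) and 46.0-fold lower (7.94 to 1850). With 1 read the order of these falls is not resolved. Among the largest rises, miR-7115-5p had 0 reads in both WT libraries and was at least 7.4-fold higher (edgeR adjusted p = 0.00747), a call that was lost without WT replicate 2 (adjusted p = 0.131). miR-1950 (4.74, SE 1.463, edgeR adjusted p = 0.00827) lost its call without either WT library (adjusted p up to 0.0659). On 1 and 2 WT reads, miR-1950 and miR-7036-5p (fitted 4.41, SE 1.11) had ratios of 27.4-fold, with counting intervals of 4.41 to 1130 and 7.13 to 234. miR-5621-5p changed by 4.18 (SE 0.927), miR-5130 by 3.93 (SE 0.816, edgeR adjusted p = 0.00102) and let-7b-3p by 3.74 (SE 0.982). miR-429-5p, a minor arm of an epithelial miRNA, changed by 4.10 (SE 1.132), and miR-15b-3p by 3.71 (SE 1.103); for both, the WT and Drosha cKO libraries overlapped on the TMM scale. Without the shallow Drosha cKO libraries the calls of miR-7115-5p, miR-1950, let-7b-3p, miR-429-5p and miR-15b-3p were lost, and that of miR-1950 also without a low-count filter.

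Of the 56 named and called features in Drosha cKO sperm, 17 lost the call without at least 1 library. Rises numbered 29 without WT replicate 1, 43 without WT replicate 2, 26 without Dicer cKO replicate 1, 31 without Dicer cKO replicate 2 and 31 without the shallow Drosha cKO libraries, against 74. With library totals alone the median of all tested features was 1.04 and rises made up 60.1% of calls, with the authors' divisor these were −0.04 and 18.6%, and in the fit with TMM 0.05 and 40%.

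The next comparison asked how far the losses of Dicer and Drosha changed the same features. In both knockouts 99 features were lower and 34 were higher, and 0 moved in opposite directions. Independent lists of the same sizes would share 34.5 and 11.9. In 100 simulations of unchanged groups tested against the same WT libraries, the mean overlaps were 0 and 0.02. The simulated groups had almost no calls to share, with means of 0.08 and 0.03 lower and 0.04 and 0.08 higher, so these overlaps are near 0 for that reason and give no measure for 99 and 34. Across features, the log2 changes correlated at 0.878, where the simulations gave a mean of 0.439 and a highest value of 0.565. The covariance was 5.98 against 0.384 in the simulations, a difference of 5.60. The same sign was seen for 85.4% of features, against 66.0% in the simulations. Both comparisons share the 2 WT libraries, which are too few to be divided between them, so part of the overlap may come from shared controls. The overlap of rises was 12 without WT replicate 1, 20 without WT replicate 2, 6 without Dicer cKO replicate 1 and 11 without Dicer cKO replicate 2.

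In the direct test of Dicer cKO against Drosha cKO sperm, edgeR called 0 of 335 features, with 65 at an unadjusted p under 0.05, while DESeq2 called 16 (3 higher and 13 lower in Dicer cKO) and limma called 2. The edgeR count was 36 without WT replicate 1, 39 without WT replicate 2, 7 without Drosha cKO replicate 2 and 1 without Dicer cKO replicate 1. The lowest edgeR adjusted p, 0.0694, belonged to miR-34b-3p (log2 difference −1.97, SE 0.478), miR-451a (1.66, SE 0.415) and miR-8101 (−2.67), the last chosen after its value was seen. Camera placed 4 of the lists apart. Blood cell markers were higher in Dicer cKO sperm (median difference 1.11, camera adjusted p = 0.0011; adjusted p = 0.378 with an estimated correlation), with 3 members higher adjusted over the list alone. The miR-30 family was higher as well (1.06, camera adjusted p = 0.00777; adjusted p = 0.504 with an estimated correlation), with 2 members higher adjusted over the list alone. The miR-34 and miR-449 family was lower in Dicer cKO sperm (−1.29, camera adjusted p = 0.0295; adjusted p = 0.59 with an estimated correlation), with 5 members lower adjusted over the list alone. Its call was lost without WT replicate 1 (0.1), Dicer cKO replicate 1 (0.085) or Dicer cKO replicate 2 (0.157), with the authors' divisor (0.155), with only the 2 groups compared (0.0725), without a low-count filter (0.399) and with at least 10 CPM in 2 libraries (0.388). Endo-siRNAs were lower (−1.61, camera adjusted p = 0.0295; adjusted p = 0.504 with an estimated correlation), with 5 lower and 1 higher adjusted over the list alone. That call was lost without Dicer cKO replicate 2 (0.103) or Drosha cKO replicate 3 (0.0934), with library totals alone (0.0644) and with only the 2 groups compared (0.0667). The remaining lists did not pass camera in this comparison: X-linked testis miRNAs (median 0.01), let-7 (−0.38), miR-17-92 (0.45), the cluster of miR-183, miR-96 and miR-182 (−0.17), Dlk1-Dio3 (−1.45), Sfmbt2 (−0.46), the group of miR-10, miR-99, miR-100 and miR-125 (0.56), miRNAs made without Drosha's complex (−0.93), epithelial markers (0.30) and stromal markers (0.66). The miR-290-295 pair (−1.03) was not tested as a list. Of these medians, that of the X-linked miRNAs turned negative with library totals alone, among other settings. Those of let-7, the miR-183 cluster and Sfmbt2 turned positive with the authors' divisor, which also gave camera calls for Sfmbt2 and the miR-10 group (adjusted p = 0.0417 each); the miR-10 group was called with both other low-count filters too (6.66e-06 and 0.00521). Camera called Sfmbt2 without Dicer cKO replicate 2 (0.0292) or Drosha cKO replicate 1 (0.0494), and the miR-10 group without WT replicate 1 (0.0313), WT replicate 2 (0.0468), Dicer cKO replicate 2 (0.0273) or Drosha cKO replicate 1 (0.00473).

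**Figure D2:**
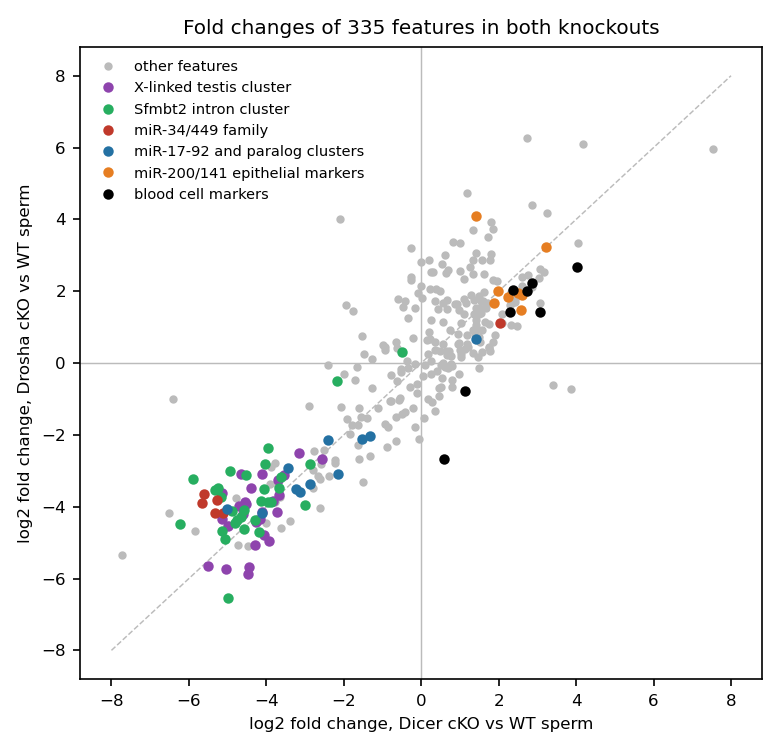
Log2 change of the 335 tested features in Dicer cKO sperm (x axis) and Drosha cKO sperm (y axis), each against WT sperm, with 6 lists in colour and a dashed line of equal change. Lower in both were 99 features and higher in both were 34; fitted values of features with a group at 0 reads are no bounds.

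WT sperm, oocytes and 2PN embryos were then compared to describe which sperm small RNAs are found in the zygote. The oocyte library was dominated by miR-30c-5p at 27.3% and miR-183-5p at 25.5% of listed reads, and the 2PN library from WT sperm by the same pair at 22.1% and 20.01%. miR-183-5p was 1041-fold and 1047-fold higher in CPM in the oocyte library than in the WT sperm libraries. Listed reads were 0.489% of the authors' divisor in oocytes and 2.16% and 10.1% in WT sperm. In RPM rises are thus smaller and falls larger. miR-195a-5p, of the miR-15 and miR-16 family, was 107-fold and 62.2-fold higher. The liver miRNA miR-122-5p was at least 535-fold higher against the sperm library with 0 reads. The imprinted miR-376b-3p was at least 336-fold higher against that library. Against the other, with 1 read of each, the ratios were 6100-fold (counting interval 1070 to 243000) and 3830-fold (667 to 153000). Several abundant sperm miRNAs were scarce in oocytes. On 2 oocyte reads miR-19b-3p was 253-fold (counting interval 69.9 to 2090) and 280-fold lower (77.5 to 2310). On 3 reads miR-34b-5p was 123-fold (42.1 to 597) and 134-fold lower (45.8 to 649), and on 4 reads miR-191-5p was 98.6-fold and 54.8-fold lower. miR-19a-3p was at least 56.2-fold and 81.3-fold lower and miR-18a-5p at least 49.0-fold and 62.0-fold lower, with 0 oocyte reads. The Spearman correlation across features was 0.646 between the 2PN and oocyte libraries and 0.102 and 0.176 between the oocyte and sperm libraries.

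Between the 2PN library from WT sperm and the oocyte library, 2 of 14 features with at least 50 reads differed by over 2-fold. miR-23a-3p was 2.37-fold higher in 2PN (interval of the ratio 1.79 to 3.16), and miR-155-5p, a miRNA of activated leukocytes, was 2.83-fold lower (ratio 0.167 to 0.686; 11 against 53 reads). Detection at 3 reads and 10 CPM gave 366 features in both WT sperm libraries, 103 in the oocyte library and 85 in the 2PN library, of which 57 were shared between 2PN and sperm and 64 between 2PN and oocyte. Features found in sperm and 2PN with 0 reads in the oocyte library numbered 3: miR-19a-3p with 4 reads, miR-466g with 4 and miR-92a-3p with 5, named after their values were seen. Of the features found in WT sperm, 234 had 0 oocyte reads. These held 24.4% and 24.3% of listed reads in WT sperm, and 51 of 3243 reads (1.57%, interval 1.17 to 2.06) in the 2PN library from WT sperm. The oocyte library was at 0 by the choice of features (0 of 5530, which allows up to 0.067%).

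2PN embryos from cKO sperm were compared with those from WT sperm to ask whether the sperm's small RNA loss was seen in the zygote. The comparison depends on scaling, because TMM factors of 1, 0.818 and 0.490 for 2PN from WT, Dicer cKO and Drosha cKO sperm raise every ratio to WT, most of all for Drosha cKO. The miR-290-295 cluster, which marks early embryos, was lower in both: it held 4.84% of listed reads (4.13 to 5.64) in 2PN from WT sperm, 0.542% (0.310 to 0.879) from Dicer cKO sperm and 1.55% (1.30 to 1.83) from Drosha cKO sperm, and 3.42% (2.95 to 3.93) in the oocyte library. Its median log2 ratios, −2.83 and −1.88, lay at percentiles 0.16 and 4.34 of 10000 random lists of like expression. With TMM its ratios to 2PN from WT sperm were 0.137 (0.076 to 0.229) and 0.653 (0.516 to 0.826). The 234 features found in WT sperm and at 0 in the oocyte library held 0.508% (0.285 to 0.837; 15 reads) from Dicer cKO sperm and 0.636% (0.482 to 0.823; 57 reads) from Drosha cKO sperm, against 1.57% from WT sperm. With TMM the ratios to WT were 0.395 (0.206 to 0.714) for Dicer cKO and 0.825 for Drosha cKO, whose interval of 0.555 to 1.23 includes no change. The Dlk1-Dio3 cluster held 2.28% (1.80 to 2.86) from WT sperm, 0.881% (0.576 to 1.29) from Dicer cKO sperm and 0.647% (0.492 to 0.835) from Drosha cKO sperm; with TMM its ratios were 0.472 (0.290 to 0.747) and 0.578 (0.403 to 0.827). With 1 library per group, none of these differences can be set against a spread between libraries.

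Among 8 features with at least 50 reads, 1 was over 2-fold higher and 3 were over 2-fold lower in 2PN from Dicer cKO sperm. miR-7a-1-3p was 2.42-fold higher (2.02 to 2.91; 385 against 175 reads) and miR-30c-5p 1.73-fold higher (1.57 to 1.90). miR-23a-3p was 5.24-fold lower (ratio 0.114 to 0.305; 21 against 121 reads), the liver miRNA miR-122-5p 2.3-fold lower (ratio 0.297 to 0.628) and miR-23b-3p 2.05-fold lower (ratio 0.376 to 0.631). let-7f-5p was 1.62-fold and miR-195a-5p 1.56-fold lower, and miR-183-5p was 1.12-fold lower with an interval of the ratio from 0.796 to 1.004. With TMM the miR-183-5p ratio turned to 1.09, that of let-7f-5p was 0.756 with an interval of 0.538 to 1.05, and those of miR-122-5p (1.88-fold) and miR-23b-3p (1.68-fold lower) came under 2-fold. The rises grew, miR-30c-5p to 2.11-fold (1.92 to 2.32) and miR-7a-1-3p to 2.95-fold (2.47 to 3.55), while miR-23a-3p stayed 4.29-fold and miR-195a-5p 1.28-fold lower. In 2PN from Drosha cKO sperm 2 of 13 features were over 2-fold higher and 3 over 2-fold lower. miR-155-5p was 3.19-fold higher (1.71 to 6.60; 97 against 11 reads) and let-7b-5p 3.07-fold higher (1.59 to 6.64; 85 against 10 reads). The p53-regulated miR-34a-5p was 1.78-fold higher (1.15 to 2.86), miR-7a-5p 1.54-fold (0.869 to 2.92), miR-195a-5p 1.51-fold, miR-192-5p 1.47-fold, miR-183-5p 1.39-fold (1.27 to 1.52) and miR-30c-5p 1.33-fold. miR-23a-3p was 5.15-fold lower (ratio 0.141 to 0.265), miR-23b-3p 2.42-fold lower (ratio 0.340 to 0.502), miR-7a-1-3p 2.03-fold lower (ratio 0.403 to 0.601) and miR-122-5p 1.09-fold lower. These ratios are of shares of listed reads. With TMM 3 of these 4 falls for Drosha cKO were not kept: miR-7a-1-3p had a ratio of 1.004 (0.822 to 1.23), miR-23b-3p was 1.19-fold lower (ratio 0.693 to 1.03) and miR-122-5p turned to 1.87-fold higher (1.49 to 2.37). miR-23a-3p remained lower, at 2.53-fold (ratio 0.289 to 0.540). The rises grew to 6.51-fold for miR-155-5p, 6.27-fold for let-7b-5p, 3.63-fold for miR-34a-5p, 3.15-fold for miR-7a-5p, 3.08-fold for miR-195a-5p, 2.99-fold for miR-192-5p, 2.83-fold for miR-183-5p and 2.71-fold for miR-30c-5p.

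The groups that dominate WT sperm held small shares in oocytes and 2PN embryos. The miR-17-92 group held 0.597% in the oocyte library and 1.26% (0.909 to 1.71), 0.373% (0.186 to 0.666) and 0.915% (0.728 to 1.13) in 2PN from WT, Dicer cKO and Drosha cKO sperm. The miR-34 and miR-449 family held 1.28% in the oocyte library and 1.17%, 1.86% and 1.49% in these 2PN libraries. With TMM the miR-17-92 ratio to WT was 0.360 (0.167 to 0.714) for Dicer cKO and turned to 1.48 (1.003 to 2.20) for Drosha cKO. That of the miR-34 and miR-449 family, mostly miR-34a-5p here, went from 1.59 (1.03 to 2.47) to 1.94 (1.26 to 3.02) for Dicer cKO and from 1.28 (0.884 to 1.88) to 2.60 (1.80 to 3.84) for Drosha cKO. That of the let-7 family went from 0.805 to 0.984 (0.769 to 1.26) and from 1.15 (0.964 to 1.38) to 2.35 (1.97 to 2.82). The let-7 family's median ratios lay at percentiles 45.3 and 74.9 of random lists. Endo-siRNAs held 0.235% in the oocyte library and 0.185%, 0.034% and 0.045% in the 2PN libraries, on 1 to 13 reads each. Epithelial markers had 0 of 2951 reads in 2PN from Dicer cKO sperm, which allows a share of up to 0.125%.

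**Figure D3:**
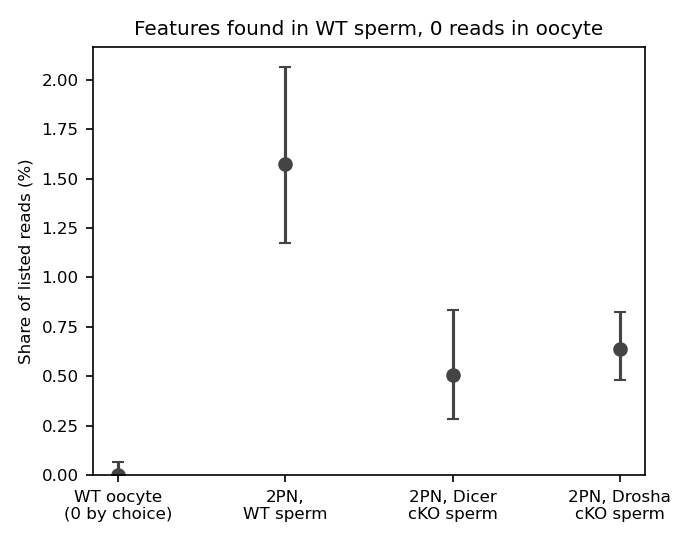
Share of listed reads (%, linear axis) of the 234 features found in both WT sperm libraries with 0 reads in the oocyte library; points are single libraries and bars are 95% exact intervals. The share is 1.57% in 2PN from WT, 0.508% from Dicer cKO and 0.636% from Drosha cKO sperm. It is 0 in the oocyte library by the choice of features. With TMM the Drosha cKO ratio is 0.825 (0.555 to 1.23).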

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

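The comparison of directions in sperm and in 2PN embryos was chosen after the data were seen, as was its move from plain CPM to the TMM scale used in the sperm comparisons, which changed the set of results that met it. It covered 19 pairs of a feature and a knockout, and 6 of them had every sperm library on 1 side of WT and the 2PN library on the other, with an interval of the 2PN ratio, in shares of listed reads, that excludes no change. The differences between sperm and 2PN were not tested, and each 2PN value rests on 1 library.

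Against WT, let-7f-5p had a log2 ratio of −0.69 in 2PN from Dicer cKO sperm (58 against 103 reads, ratio 0.441 to 0.862, or 0.538 to 1.05 with TMM factors for 2PN, which includes no change) and a log2 change of 1.28 (SE 0.472, edgeR adjusted p = 0.0353) in Dicer cKO sperm. The sperm call was lost without either WT or either Dicer cKO library. miR-23a-3p had −2.39 in 2PN from Dicer cKO sperm (21 against 121 reads, ratio 0.114 to 0.305) and 1.76 (SE 0.559, edgeR adjusted p = 0.0161) in sperm, a call that was also lost without either WT or either Dicer cKO library. miR-30c-5p had 0.79 in 2PN from Dicer cKO sperm (1126 against 717 reads, ratio 1.57 to 1.90) and −1.33 (SE 0.508, edgeR adjusted p = 0.0403) in sperm, a call that was lost without any library except WT replicate 1 (adjusted p up to 0.18, without Dicer cKO replicate 1). miR-7a-1-3p had 1.27 in 2PN from Dicer cKO sperm (385 against 175 reads, ratio 2.02 to 2.91) and −1.71 (SE 0.878, edgeR adjusted p = 0.121) in sperm. miR-195a-5p had 0.59 in 2PN from Drosha cKO sperm (998 against 239 reads, ratio 1.31 to 1.75) and −1.73 (SE 0.624, edgeR adjusted p = 0.0275) in sperm. That call was lost without WT replicate 2, Drosha cKO replicate 1 or 3, or the shallow Drosha cKO libraries. It was also lost without a low-count filter, and with library totals alone, at least 10 CPM in 2 libraries, limma or the authors' divisor. With library totals alone its sperm libraries were not all on 1 side of WT. miR-30c-5p had 0.41 in 2PN from Drosha cKO sperm (2632 against 717 reads, ratio 1.22 to 1.44) and −2.59 (SE 0.462, edgeR adjusted p = 0.00034) in sperm.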

How the results depend on the processing

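The authors' divisor, miRNAs only, the mean of at least 200 CPM and the removal of the 2 shallow Drosha cKO libraries were chosen after seeing the data; the other alternatives were planned. No named feature or list called against WT in sperm changed direction under the alternatives. Medians of lists short of the camera threshold did change sign, among them Dlk1-Dio3 in Dicer cKO (−0.39 to 0.36 with library totals alone), the miR-30 family in Dicer cKO (−0.64 to 0.04) and the endo-siRNAs in Drosha cKO (−0.08 to 1.57 without WT replicate 1). The blood cell list in Drosha cKO went from 4 rises and 1 fall to 0 and 2 without WT replicate 1. Over the alternatives the edgeR count for Drosha cKO against WT moved beyond 1.5 times its 185 only without a low-count filter, to 112, where 2186 features were tested in place of 335; that for Dicer cKO, 158, never did. Leaving out 1 library gave 112 to 174 for Dicer cKO, 153 to 185 for Drosha cKO and 0 to 39 for Dicer cKO against Drosha cKO (36 without WT replicate 1, 39 without WT replicate 2); where this leaves 1 library in a group, it is assumed to vary like the other groups. The count of 0 between the knockouts became 13 with library totals alone, 1 without a filter, 4 with at least 10 CPM in 2 libraries, 16 with DESeq2, 2 with limma, 31 with only the 2 groups compared, 8 with the replicate block, 1 with the authors' divisor and 3 at a mean of at least 200 CPM. Only replicate numbers 1 and 2 are shared by all groups and no label pairs the libraries; deviations of libraries with the same number correlated at 0.312 (WT and Dicer cKO), 0.251 (WT and Drosha cKO) and 0.264 (Dicer cKO and Drosha cKO), which with 2 shared numbers does not pair them. The replicate block gave 175 for Dicer cKO and 184 for Drosha cKO, where miR-182-5p and miR-125b-5p were not called. In its list tests the camera call of endo-siRNAs between the knockouts was lost (adjusted p = 0.118), the miR-10 group passed camera in Drosha cKO (0.0352), and by fry no list passed in Drosha cKO (lowest adjusted p = 0.0673) while 3 marker lists did in Dicer cKO (0.0499). Features lower in both numbered 99, 62 with limma and 88 to 110 without 1 library. Features higher in both, 34, numbered 86 with library totals alone, 2 without a filter, 21 with at least 10 CPM in 2 libraries, 15 with limma, 6 with the authors' divisor, 13 without the shallow libraries, and 6 (without Dicer cKO replicate 1) to 42 (without Drosha cKO replicate 2) without 1 library. Lists past camera numbered 7, 6 and 4 for Dicer cKO, Drosha cKO and the difference between them. They became 12, 13 and 9 without a filter, 12 for Dicer cKO and 8 for the difference with at least 10 CPM in 2 libraries, and 2 for the difference with only the 2 groups compared; without 1 library they ranged over 7 to 8, 5 to 8 and 3 to 6. In 2PN from Dicer cKO sperm 4 features were over 2-fold apart, and 12 with a minimum of 20 reads. From Drosha cKO sperm 5 were, and 10 with TMM, 15 with a minimum of 20 reads and 3 with 100. Features in sperm and 2PN with none in the oocyte library numbered 3, 0 at 10 reads and 50 CPM, and 14 with at most 2 reads as absent; those in 2PN and oocyte numbered 64, and 23 at 10 reads and 50 CPM. Except where fewer or more features pass a filter, the cause was not tested. Of 466 alternative camera tests of single lists 427 kept their side of the threshold, 32 moved past it and 7 fell short of it, while 36 list values had no test; of 2682 for named features 2412 kept it, 49 moved past it and 221 fell short. Lists were not run with DESeq2, as planned, and limma gave no list count. Depth limits the smaller changes: with 12003 and 15921 reads, 3 reads in the shallow Drosha cKO libraries are 249.9 and 188.4 CPM, and in 2PN embryos 3 reads are 334.6 to 1016.6 CPM.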

Other observations

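The features of the first paragraphs here, and all tests below except the test with oocyte and 2PN exchanged, were chosen after the results were seen; for the marker lists a pooled test of both knockouts was replaced, after its result was seen, by a stricter test for each knockout.

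Several miRNAs outside the lists rose in both knockouts. miR-205-5p, an epithelial miRNA, rose by 2.59 on the log2 scale (SE 0.604, edgeR adjusted p = 0.00211) in Dicer cKO sperm and by 2.14 (SE 0.570, edgeR adjusted p = 0.00565) in Drosha cKO sperm. Its first call was lost without Dicer cKO replicate 1 and its second without WT replicate 2 or either Dicer cKO library. The clustered miR-221-3p and miR-222-3p rose by 2.34 (SE 0.549) and 2.77 (SE 0.672) in Dicer cKO sperm and by 1.67 (SE 0.511) and 2.44 (SE 0.638) in Drosha cKO sperm. Their Drosha calls were lost without WT replicate 1, and that of miR-221-3p also without either Dicer cKO library. miR-101a-3p rose by 3.04 (SE 0.681) and 2.37 (SE 0.643), the latter call being lost without WT replicate 1 or Dicer cKO replicate 1. All 4 Drosha calls were lost besides with the authors' divisor, without a low-count filter and without the shallow Drosha cKO libraries, and that of miR-221-3p with limma, at least 10 CPM in 2 libraries or only the 2 groups compared. Falls outside the lists included miR-425-5p, a neighbour of miR-191, at −3.72 (SE 0.660) and −3.37 (SE 0.559). miR-128-3p changed by −4.02 (SE 0.794) and −4.44 (SE 0.730), miR-375-3p, known from endocrine cells, by −3.91 (SE 0.956) and −3.36 (SE 0.823), and miR-301a-3p by −3.66 (SE 0.782) and −3.74. The calls of these 4 falls held without any 1 library, though that of miR-375-3p in Drosha cKO sperm was lost without both shallow libraries (adjusted p = 0.0672).

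A further 3 miRNAs were called higher in Drosha cKO sperm and not in Dicer cKO sperm. miR-3960 changed by 3.34 (SE 0.686, edgeR adjusted p = 0.000994) there and by 1.01 (edgeR adjusted p = 0.229) in Dicer cKO sperm. miR-149-3p changed by 3.37 (SE 0.739, edgeR adjusted p = 0.00155) and 0.82 (edgeR adjusted p = 0.379), and miR-8101 by 2.88 (SE 0.576, edgeR adjusted p = 0.000794) and 0.21. The direct test between the knockouts did not call them (edgeR adjusted p = 0.082 for miR-3960 and miR-149-3p and 0.0694 for miR-8101).

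Blood cell marker miRNAs rose in Dicer cKO sperm but did not pass camera in Drosha cKO (adjusted p = 0.0628). Their RPM sums there were 609, 662 and 540 against 117 and 531 in WT. Epithelial markers rose in both knockouts, where germ cell miRNAs fell. Whether fewer sperm miRNA reads within the listed reads are the whole cause stays open, since what the authors' divisor counts is unknown. With it 7 of 8 epithelial markers were higher in Dicer cKO sperm (median 3.02, fry adjusted p = 0.0651). In RPM the list summed to 343 and 1833 in WT, 5799 and 11334 in Dicer cKO, and 3106, 4153 and 2443 in Drosha cKO. For Drosha cKO sperm the median went from 1.92 to 1.60 with that divisor and the median SE from 0.522 to 0.913. Calls went from 8 to 1 of 8, mostly through the wider spread, and the list passed camera (adjusted p = 0.0048) but not fry (0.156). A lower share of sperm cells in the pellet, with other cells in unchanged proportion, stays open. Epithelial markers gained 0.92 on blood cell markers (SE 0.186) in Drosha cKO, but values at few reads depend on depth. In Dicer cKO the widest gap, blood over stromal, was 1.38 (SE 0.581). Whether RNA of other cells or a change in sperm themselves underlies the rise stays open, and a biological change was not tested: both WT libraries held at least 3 reads for 6 of 8 tested epithelial, 7 of 7 stromal and 7 of 8 blood cell markers, 0 members are shared between lists, and the labels give a pelleting step and no sort of sperm.

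In WT sperm replicate 1, 711 of 712 listed endo-siRNAs had a read, 511 of them 1 read, against 160 in WT replicate 2 and 24 to 139 in cKO sperm. Deeper sequencing is argued against, because at 12003 reads that library still detected 3.63 times the highest of the others, and so is the WT genotype, because WT replicate 2 detected 23.63 on average, inside the range of the cKO libraries. Whether the endo-siRNA list was drawn up from reads of that library stays open: that 7.52 times as many had a read as the other sperm libraries' levels give restates the pattern and decides nothing. The list's origin is not given in the sources used here, so a fall of rarely read endo-siRNAs in cKO sperm is not shown by detection alone.

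Features found in WT sperm with 0 oocyte reads held 1.57% of listed reads in 2PN from WT sperm. The share was 0.508% from Dicer cKO and 0.636% from Drosha cKO sperm (TMM ratio 0.825, 0.555 to 1.23). RNA carried in by sperm in WT proportions stays open as the sole source. The 51 reads fell on 37 features against 20 to 32 in 10000 draws, which cover counting error only. The choice of features for 0 oocyte reads may account for part of the share: chosen instead for 0 reads in 2PN, such features held 1.274% (0.925 to 1.573 over 100 thinnings) of the oocyte library at 3243 reads, against 2.369% (1.758 to 3.484) for the original direction at that depth. The original direction lay above the exchanged one in these thinnings, but they cover thinning alone and each stage has 1 library, where sperm replicates differed by far more than counting error; how much the choice accounts for stays open, as does delivery of RNA by sperm in other proportions, which was not tested.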
